A study of Mus musculus with 8 samples.

How the data were processed

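Strand-specific polyA libraries were made from sorted mouse pancreatic cancer cells and sequenced in paired reads, per the labels' protocols, in 2 arms of 4 libraries each. Per the submitters' processing notes, base calls were made with CASAVA 1.8.2 and reads were aligned with TopHat2 2.0.9 to the mouse genome GRCm38. The counting tool, the annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of raw counts per Ensembl gene and 1 table of RPKM values for the same 8 libraries. The deposited count table lists 39179 genes with symbols, of which 21392 had a count in at least 1 library, and 253 symbols occur more than once. Over 15265 genes checked, the authors' RPKM values equalled the count divided by 1 gene length and by the library's column total, with lengths whole within 0.01 bases, so they carry no further scaling.

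Samples were grouped by the treatment in the labels. In the sample titles a minus sign marks the libraries with antibody. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjustment at 0.05), with the arm as the only term. The filter left 13626 genes. Every fold change is antibody over no antibody, with a standard error from the F statistic. CPM values are counts scaled to a common library total with TMM factors (edgeR), given as mean ± SD over 4 libraries. Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) where at least 5 members had been tested, and again with an estimated correlation and with fry. Adjusted p of lists are over 34 lists. Library totals and shares were compared by exact two-sided permutation over the 70 assignments of libraries to arms, which can give no p below 0.0286. A count of 3 corresponds to between 0.191 and 0.30 CPM in these libraries, and such floors cover counting error only. The standard errors and intervals of fold changes also take in the spread between the libraries of an arm. In the fit without a filter on low counts this spread was taken from all genes together, so its calls do not weigh a gene's own spread.

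The test, the alternatives, the 37 gene lists and the rule for the genes named were fixed before the data were examined. The rule names Shh, Ptch1, Gli1, Igf1r and Axl, among others. It adds the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM whose arms do not overlap, leaving out predicted genes and pseudogenes. It also takes the 4 genes with the smallest adjusted p and up to 4 members with the smallest p of each list. Of the genes that the rule takes, 3 are not reported here. H2-D1, which the rule takes as a member with a small p in its list, was taken up only after its value was seen. The lists hold 774 genes, of which 670 were tested, and none is in more than 1 list. Camera asks whether a list moves relative to all other genes, and fry whether its genes move, on balance, one way. With the estimated correlation 0 of the 34 lists were called at adjusted p under 0.05, while fry called 12. At unadjusted p under 0.05 the estimated correlation left the mesenchymal, ERK, interferon, inflammatory, ATF4 and YAP/TAZ lists.

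The procedure was tested on simulated counts drawn from the means, library sizes and dispersions of these libraries for this comparison. The test held 13523 genes, with 200 genes drawn at random changed and the glycolysis list shifted as well. Of changed genes with a fold of 1.25, 53.7% were recovered, of those with 1.5, 81.5%, and of those with 2, 97%, and 5.17% of the calls were false. In the same simulation camera called the shifted glycolysis list and 0 of the 33 other lists, and fry called 4 of them. The simulated genes were drawn independently of each other, with the same dispersion in both arms. These shares therefore do not cover correlation between genes or an unequal spread of the arms. Changed genes made up 1.6% of those in the simulated test, where 8.4% were called in the data, so the recovery there can differ.

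Alternatives tried were RLE and upper quartile scaling, no filter and a stricter filter on low counts, the replicate number as a block, the level of stellate markers as a covariate, DESeq2 1.42.0, limma voom, a minimum fold of 1.2, the authors' RPKM values as log2(RPKM + 1) and log2(RPKM + 0.1), and leaving out each library in turn. Chosen after the data had been seen were voom with sample weights, thinning of all libraries to the smallest total, removal of trends with gene length and GC content, and leaving out replicates 1 and 4 without antibody. These stand apart from replicates 2 and 3, which differ from each other by a chi-square over degrees of freedom of 1.85, while replicate 4 differs from them by 4.93 and 4.19 and replicate 1 from the other 3 by 10.1 to 12.3. No 2 libraries of an arm agreed within sampling noise (chi-square over degrees of freedom 1.77 to 3.99 between antibody libraries and 1.85 to 12.3 between the others), so each was counted as 1 sample. Genes that overlap another gene can hold its reads. Of the genes that the rule takes and that are named here, this concerns Il1a, Angptl6, Esrp2, Pfkp, Ccne2 and Ccna2 on the opposite strand. On the same strand it concerns Sprr2a1 and Acsl3. Genes named outside the rule were not checked for overlap.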

Results

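The libraries measured the polyA RNA of mouse pancreatic epithelial cancer cells that carry a green fluorescent label. The cells had been grown for 72 h together with red-labelled pancreatic stellate cells, the fibroblast-like cells of the pancreas, in medium with 0.5% dialyzed serum. One arm of 4 libraries received 20 µg/mL of an antibody that neutralizes sonic hedgehog (SHH), and the other arm of 4 libraries received no antibody. The cultures were dissociated and sorted by colour, and only the green cancer cells were sequenced. SHH is a secreted ligand, and the comparison asks which transcripts of the cancer cells differ when it is neutralized in a culture that also holds stellate cells. The labels describe 4 biological samples per arm. They name no control antibody in the other arm.

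Each library assigned between 10009711 and 15733280 counts to genes. The antibody libraries held 15411257, 15733280, 15156461 and 14953255 counts and the libraries without antibody 13017496, 10009711, 10670776 and 14602784, so that every antibody library was deeper than every other library. The mean totals were 15310000 ± 336800 and 12080000 ± 2123000 (SD, n = 4 each; two-sided exact permutation p = 0.0286, or 0.114 after Benjamini-Hochberg adjustment over 4 library measures). Mitochondrially encoded mRNAs took 4.35% ± 0.37 of counts with antibody and 4.78% ± 0.97 without (exact permutation p = 0.571, n = 4 each). The 10 most abundant genes took 6.61% ± 0.32 and 6.93% ± 0.95 (exact permutation p = 0.8, n = 4 each). Replicate 1 of the arm without antibody stood apart, with 6.21% of its counts in mitochondrially encoded mRNAs.

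**Figure D1:**
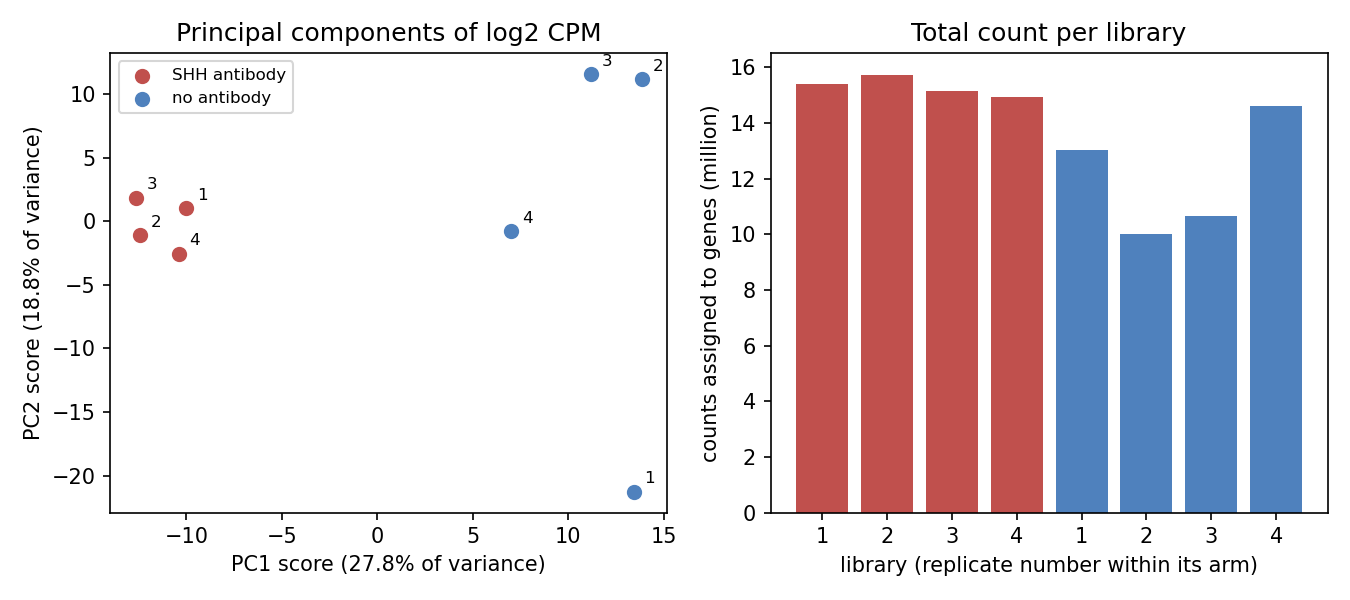
Left, the scores of the 8 libraries on the first and second principal components of log2 CPM, which hold 27.8% and 18.8% of the variance, with the replicate number beside each point. Right, the total count of each library as bars that start at 0. The first component separates the arms, and the 4 antibody libraries lie close together while replicate 1 without antibody lies apart on the second.

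Stellate cell RNA was scarce in the sorted cancer cells of both arms. The 26 stellate and fibroblast markers took 0.0229% ± 0.0024 of counts with antibody and 0.0205% ± 0.0027 without (SD, n = 4 each; exact permutation p = 0.171). Col1a1, the chain of type I collagen that stellate cells make in abundance, stood at 15.06 ± 3.87 CPM against 11.66 ± 2.53 CPM (log2 fold change 0.36, adjusted p = 0.169). It was called as higher without a filter (adjusted p = 0.00616), a fit that does not weigh the gene's own spread. It was also called without replicate 3 of the antibody arm (0.49, adjusted p = 0.0458), without replicate 1 of the other (0.53, adjusted p = 0.0153) and without replicates 1 and 4 of the other (0.55, adjusted p = 0.0189). Of the 15 markers tested, Gas6, which encodes the ligand of AXL, rose (log2 fold change 0.42 ± 0.12 SE, adjusted p = 0.0339) and Pdgfra, a PDGF receptor, fell (log2 fold change -0.84 ± 0.17 SE, adjusted p = 0.00271). Gas6 kept its call in 2 of the 8 fits without a single library, and lost it with the replicate block (adjusted p = 0.0544), DESeq2 (adjusted p = 0.058) and on log2(RPKM + 1) (adjusted p = 0.0605) and log2(RPKM + 0.1) (adjusted p = 0.0632). The same 2 genes passed when adjusted over the list alone. The list was not called (adjusted p = 0.197), but it was called as higher without replicate 3 of the antibody arm (adjusted p = 0.0151) and without replicate 1 of the other arm (adjusted p = 0.0298). Markers of leukocytes (2 genes tested), endothelial cells (4) and acinar cells (1) held no called gene, and these lists were too short for a list test.

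With the antibody, lists of transcripts of the amino acid response, of ERK signaling and of inflammatory cytokines were called as lower by camera with a preset correlation, but not with an estimated correlation (adjusted p = 0.185 for each). Some transcripts of DNA replication and mitosis rose, 14 of 33 and 6 of 26. In all, 1144 of 13626 genes tested differed, 617 higher and 527 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The changes were mostly small, with a median fold of 1.23 among the called genes. A fold over 1.5 was found for 159 of them, and a fold over 2 for 36, of which 24 were higher and 12 lower. The values of the arms did not overlap in 1944 genes, 14.3% of those tested, where chance gives 2.86%. The spread between libraries, as the biological coefficient of variation, was 3.25% within the antibody arm and 7.01% within the other. Without replicate 2 of the antibody arm 679 genes were called, and without replicate 3 of that arm 695.

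Among called genes of at least 1 CPM whose arms do not overlap, the 8 largest rises were those of Fut2, Bcas1, Sptssb, Sprr2a3, Sprr2a1, Tspan1, Cyp2c65 and Nepn. Fut2, a fucosyltransferase that adds fucose to mucosal glycans (ENSMUSG00000055978, chromosome 7, 45648595 to 45666308, GRCm38), went from 0.592 ± 0.208 to 2.16 ± 0.279 CPM (3.56-fold, adjusted p = 0.000138). Sptssb, a subunit of serine palmitoyltransferase, rose 2.78-fold (adjusted p = 1.33e-05), and Nepn, nephrocan, 2.31-fold (adjusted p = 1.65e-06). Bcas1 rose by a log2 fold change of 1.54 ± 0.36 SE (adjusted p = 0.00823) and the tetraspanin Tspan1 by 1.36 ± 0.36 SE (adjusted p = 0.0189). Both rose from a low level, 0.619 ± 0.423 and 0.596 ± 0.206 CPM, or 2 to 15 counts per library without antibody. The cytochrome P450 gene Cyp2c65 rose by 1.31 ± 0.17 SE. Sprr2a3 (1.41) and Sprr2a1 (1.40) belong to a family of near-identical genes of the epidermal envelope, and Sprr2a1 overlaps Sprr2a2 on the same strand, so their values are uncertain.

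By the same rule the 8 largest falls were those of Il1a, Sprr2h, Angptl6, Cdsn, Extl1, Rgs16, Aldh1l2 and Gucy2g. Il1a, the cytokine interleukin 1 alpha (ENSMUSG00000027399, chromosome 2, 129299610 to 129309972, GRCm38), went from 2.35 ± 0.493 to 0.637 ± 0.092 CPM, which is 3.71-fold lower (adjusted p = 4.14e-05). An antisense transcript overlaps Il1a, and whether the counting used strand is not given, so part of its reads is uncertain. Angptl6 (-1.30), the corneodesmosin gene Cdsn (-1.29), the glycosyltransferase gene Extl1 (-1.24), the G protein regulator Rgs16 (-1.12) and the guanylate cyclase gene Gucy2g (-1.08) stood under 5 CPM in both arms. Sprr2h (-1.66) is uncertain for the same reason as its relatives. Aldh1l2, a mitochondrial enzyme of folate metabolism, was the most abundant of them, at 34.67 ± 6.17 CPM against 73.63 ± 14.51 CPM.

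Tff1, S100a7a and Ndnf were among the genes with the smallest adjusted p. Tff1, a trefoil peptide that is secreted with gastric mucus (ENSMUSG00000024032, chromosome 17, 31161396 to 31165053, GRCm38), rose from 51.72 ± 1.74 to 95.19 ± 5.10 CPM (1.84-fold, adjusted p = 1.51e-09). Ndnf, a secreted neurotrophic factor, rose 2.08-fold (adjusted p = 3.64e-08). S100a7a, an S100 protein of inflamed epithelium, was 1.86-fold lower (adjusted p = 1.3e-08).

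Hedgehog pathway genes in the cancer cells did not move together. Ptch1, the hedgehog receptor that is itself a hedgehog target (ENSMUSG00000021466, chromosome 13, 63511533 to 63565520, GRCm38), stood at 23.02 ± 1.63 CPM with antibody and 23.07 ± 1.22 CPM without. Its log2 fold change was 0.00 ± 0.07 SE (adjusted p = 0.994), and the 95% interval of the fold reached from 0.90 to 1.11. Gli1, a transcription factor and target of the pathway, had 7, 3, 2 and 3 counts with antibody and 6, 1, 2 and 4 without, too few to be tested. Shh itself had 7, 13, 16 and 8 counts with antibody and 5, 0, 7 and 0 without, and was also too low for the test. With no filter on low counts the log2 fold change of Shh was 1.49 ± 0.50 SE (adjusted p = 0.0467). That fit does not weigh the spread of Shh itself between libraries, and the counts of the arms overlap, so a rise of Shh is uncertain. Ihh, which encodes another hedgehog ligand, rose from 7.13 ± 0.976 to 13.64 ± 1.27 CPM (1.92-fold, adjusted p = 7.48e-06), while Dhh, the third ligand, had a log2 fold change of -0.16 (adjusted p = 0.112), called as lower without replicate 1 of the arm without antibody (adjusted p = 0.0303), without its replicates 1 and 4 (adjusted p = 0.0182) and with voom sample weights (adjusted p = 0.0337). Ihh was the 1 called gene among the 10 tested, also when adjusted over the list alone. The list's camera test (adjusted p = 0.608) and median (-0.03) pointed down and its mean (0.01) up.

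Among the receptors named in advance, Axl fell and Igf1r did not pass the test. Axl, a receptor tyrosine kinase whose ligand is GAS6, went from 420.1 ± 13.79 to 334.9 ± 4.72 CPM (log2 fold change -0.33 ± 0.04 SE, adjusted p = 3.52e-05). Igf1r, the receptor of insulin-like growth factor 1, had a log2 fold change of -0.19 ± 0.06 SE (adjusted p = 0.0607). It was called as lower without replicate 2 of the antibody arm (-0.24, adjusted p = 0.0339), with voom sample weights (adjusted p = 0.0471), without replicates 1 and 4 of the other arm (adjusted p = 0.0364) and after removal of length and GC trends (adjusted p = 0.0365). Of 19 genes of the receptors and the AKT pathway, Axl and Eif4ebp1, a translation repressor (-0.36), fell, and adjusted over the list alone 4 were lower and 1 higher. The list was not called (adjusted p = 0.279).

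Genes of the ATF4 and amino acid response, which cells induce when amino acids run short, were lower with the antibody almost throughout. Of 25 genes tested 23 fell and none rose, and 24 fell when adjusted over the list alone. Cth, which makes cysteine from cystathionine, went from 129.7 ± 17.55 to 64.64 ± 8.66 CPM (2.01-fold lower, adjusted p = 1.03e-07). Trib3, a pseudokinase induced by ATF4 (log2 fold change -0.84 ± 0.08 SE), and Chac1, which degrades glutathione (-0.75 ± 0.08 SE), fell as well. The median log2 fold change was -0.39, and the list was called as lower (camera, adjusted p = 3.01e-22, or adjusted p = 0.185 with an estimated correlation). In contrast, of 17 genes of endoplasmic reticulum stress Herpud1 fell (-0.34) and Edem1 rose (0.20), and adjusted over the list alone 1 was higher and 2 lower. That list was not called (adjusted p = 0.353).

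**Figure D2:**
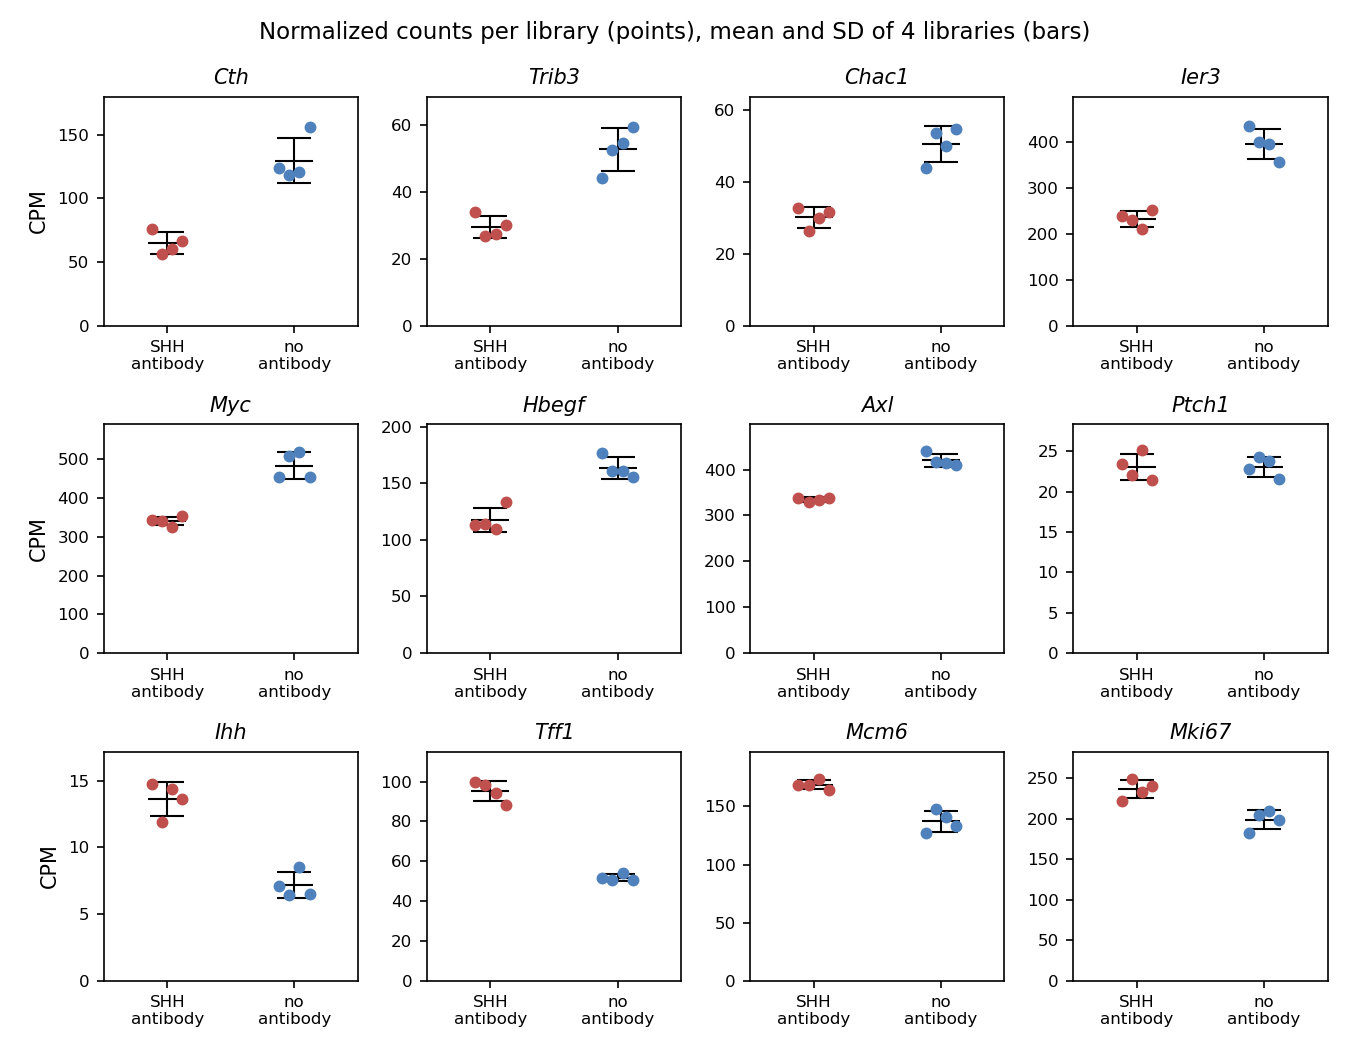
Normalized counts of 12 genes in CPM, on axes that start at 0, with a point for each library and bars for the mean and SD of 4 libraries per arm. Cth, Trib3, Chac1, Ier3, Myc, Hbegf and Axl lie lower with the antibody, Ihh, Tff1, Mcm6 and Mki67 lie higher, and the arms overlap for Ptch1.

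Several genes that report ERK signaling fell. Ier3, an immediate early survival gene, went from 396.0 ± 32.32 to 232.5 ± 17.4 CPM (1.70-fold lower, adjusted p = 4.64e-08). The transcription factor gene Myc (log2 fold change -0.51 ± 0.05 SE), the EGF receptor ligand gene Hbegf (-0.48 ± 0.06 SE) and the ERK phosphatase gene Dusp5 (-0.42 ± 0.05 SE) fell too. In all 11 of 22 genes fell and none rose, and 13 fell when adjusted over the list alone. The list was called as lower (camera, adjusted p = 5.18e-09, or adjusted p = 0.185 with an estimated correlation). Immediate early genes as a wider class were not called (adjusted p = 0.162 over 16 genes). Among them Egr1 fell (-0.63 ± 0.13 SE) and Klf4 rose (0.30 ± 0.05 SE). The arms overlap for Egr1, which lost its call with DESeq2 (adjusted p = 0.0782) and on log2(RPKM + 1) (adjusted p = 0.0581) and log2(RPKM + 0.1) (adjusted p = 0.0567). Adjusted over the list alone 4 were lower and 1 higher. That list was called as lower without replicate 4 of the antibody arm (adjusted p = 0.00164), and with the stellate marker level as a covariate (median -0.26 against -0.10, adjusted p = 0.00746).

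Several inflammatory cytokines and NF-kB targets fell. Beside Il1a, the neutrophil chemokine gene Cxcl5 fell from 67.69 ± 5.56 to 36.43 ± 4.38 CPM (adjusted p = 1.03e-07). Lif, a cytokine of the IL-6 family (log2 fold change -0.55 ± 0.07 SE), and Tnfaip3, a feedback inhibitor of NF-kB (-0.50 ± 0.05 SE), fell as well. Of 18 genes 9 fell and 1 rose, the same counts as when adjusted over the list alone. The list was called as lower (camera, adjusted p = 7.12e-05, or adjusted p = 0.185 with an estimated correlation). Of 13 interferon response genes 1 fell, Bst2, an antiviral tether of virions (-0.43 ± 0.07 SE), also when adjusted over the list alone. That list was called as lower (adjusted p = 0.038, or adjusted p = 0.262 with an estimated correlation), but not without replicate 3 of the antibody arm (adjusted p = 0.0876) or replicate 4 of the other (adjusted p = 0.0612). It was also lost without a filter (adjusted p = 0.0551), with the replicate block (adjusted p = 0.0583), on log2(RPKM + 1) (adjusted p = 0.0536) and without both control libraries that stand apart, replicates 1 and 4 (adjusted p = 0.135). Of 6 antigen presentation genes H2-K1 (-0.21) and H2-D1 (-0.14, adjusted p = 0.0481) fell, the second of which kept its call in 1 of the 8 fits without a single library, and adjusted over the list alone 2 were lower and 1 higher. These class I genes are near-identical to relatives and their values are uncertain, and the list was not called (adjusted p = 0.149), except without replicate 3 of the antibody arm (adjusted p = 0.036).

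Some mesenchymal and YAP/TAZ target genes fell, 3 of 13 and 5 of 14, and 5 of 19 epithelial genes rose. Snai2, which encodes the transcription factor Slug, fell from 14.36 ± 0.707 to 8.41 ± 0.499 CPM (adjusted p = 8.92e-06), and Twist2 (log2 fold change -0.72 ± 0.14 SE) and fibronectin, Fn1 (-0.18 ± 0.05 SE), fell too. These were the 3 called genes of 13, and 4 were lower when adjusted over the list alone (list adjusted p = 0.00383, or adjusted p = 0.185 with an estimated correlation). Of 14 YAP/TAZ targets 5 fell and none rose, and 6 fell when adjusted over the list alone. They included Cyr61 (-0.87 ± 0.10 SE), Ankrd1 (-0.52 ± 0.05 SE), the tissue factor gene F3 (-0.22 ± 0.05 SE) and Ctgf (-0.19 ± 0.05 SE). That list was called as lower (adjusted p = 0.00519, or adjusted p = 0.234 with an estimated correlation). Of 19 epithelial and ductal markers 5 rose and none fell, and 6 rose when adjusted over the list alone. Cftr, the chloride channel of duct cells, rose 1.67-fold to 22.44 ± 2.53 CPM (adjusted p = 1.72e-05), and the splicing factor gene Esrp2 (0.26 ± 0.05 SE), the adhesion gene Epcam (0.28 ± 0.08 SE) and the desmosome gene Dsp (0.21 ± 0.05 SE) rose less. Esrp2 overlaps Nfatc3 on the other strand. The epithelial list was called (adjusted p = 0.0218, or adjusted p = 0.436 with an estimated correlation), but not without replicate 1 (adjusted p = 0.0696) or 4 (adjusted p = 0.0925) of the arm without antibody. Without both of these libraries its median was 0.01 against 0.10 with all (adjusted p = 0.435).

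Part of the cell cycle genes rose by small amounts. Of 33 genes of the G1/S transition and DNA replication 14 rose and none fell, and 19 rose when adjusted over the list alone. The replicative helicase gene Mcm6 went from 137.3 ± 9.11 to 168.7 ± 3.97 CPM (1.23-fold, adjusted p = 0.000442). The cyclin gene Ccne2 (log2 fold change 0.41 ± 0.08 SE), the DNA polymerase gene Pola1 (0.33 ± 0.06 SE) and Uhrf1, which maintains DNA methylation (0.30 ± 0.06 SE), rose as well. Of 26 genes of G2/M and mitosis 6 rose and none fell, and 8 rose when adjusted over the list alone, among them Ccna2 (0.27 ± 0.05 SE), Mki67 (0.25 ± 0.05 SE) and Top2a (0.21 ± 0.05 SE). Both lists were called as higher, G1/S with adjusted p = 2.86e-09 (adjusted p = 0.317 with an estimated correlation) and G2/M with adjusted p = 9.51e-05 (adjusted p = 0.448 with an estimated correlation). Camera gave so small an adjusted p in 5 and 8 of the 35 splits of the 8 libraries. G2/M was not called by fry (adjusted p = 0.0829) or without both control libraries that stand apart (median 0.04, adjusted p = 0.312). Of 8 replication-dependent histone genes none was called, also when adjusted over the list alone, and the list was not called either (adjusted p = 0.353). Ccne2 and Ccna2 each overlap a gene on the other strand.

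**Figure D3:**
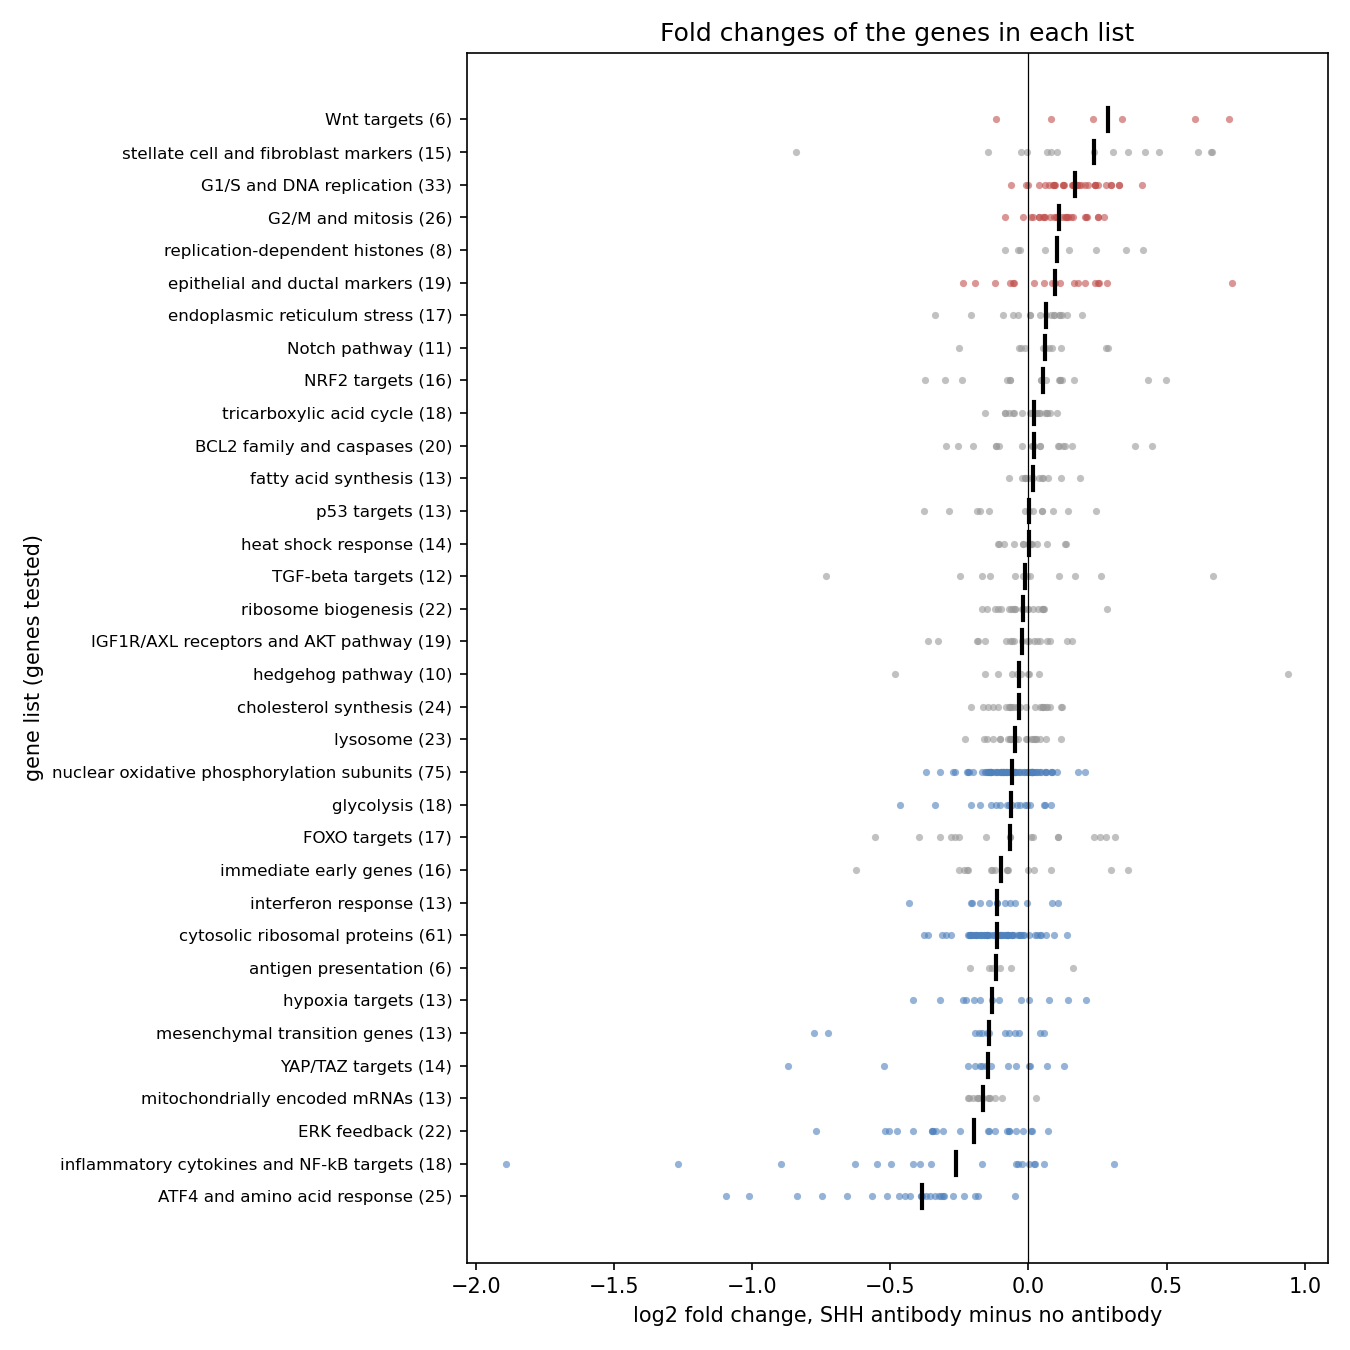
Log2 fold changes, antibody minus no antibody, of the tested genes of each list, 1 point per gene, with a black tick at the list's median and the number of genes tested in brackets. Lists called by camera with the preset correlation are red where higher and blue where lower, and the others are grey. The median of the ATF4 list is -0.39 and that of the G1/S list 0.17.

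Of 61 ribosomal protein genes 11 fell and none rose, and 19 fell when adjusted over the list alone, with a median log2 fold change of -0.11. Rpsa (-0.36 ± 0.06 SE), Rpl41 (-0.28 ± 0.05 SE), Rpl7a (-0.30 ± 0.06 SE) and Rps20 (-0.22 ± 0.05 SE) had the smallest p. Ribosomal protein genes have many processed pseudogenes that can share their reads, so these values are uncertain. The list was called as lower (adjusted p = 5e-06, or adjusted p = 0.445 with an estimated correlation). Its median was -0.06 without replicate 1 of the arm without antibody, the library with the high mitochondrial share (adjusted p = 0.00709), and fry did not call the list (adjusted p = 0.089). In 5 of the 35 splits of the 8 libraries camera gave so small an adjusted p. None of 22 ribosome biogenesis genes was called, also when adjusted over the list alone (list adjusted p = 0.438).

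Energy metabolism genes moved little. Of 18 glycolysis genes the phosphofructokinase gene Pfkp (-0.34 ± 0.05 SE), the lactate exporter gene Slc16a3 (-0.46 ± 0.08 SE) and the aldolase gene Aldoa (-0.21 ± 0.06 SE) fell, and 5 fell when adjusted over the list alone. Pfkp overlaps Pitrm1 on the other strand. The list was called as lower (adjusted p = 0.0186, or adjusted p = 0.445 with an estimated correlation), but not without replicate 2 of the arm without antibody (adjusted p = 0.0949) or with the stellate marker level as a covariate (median -0.04 against -0.06, adjusted p = 0.0658). Of 13 hypoxia targets Vegfa, the vascular growth factor (-0.42 ± 0.06 SE), Ero1l (-0.32 ± 0.06 SE) and the collagen prolyl hydroxylase gene P4ha1 (-0.24 ± 0.05 SE) fell, and adjusted over the list alone 6 were lower and 1 higher. That list was called as lower (adjusted p = 0.0306, or adjusted p = 0.317 with an estimated correlation), but not without replicate 4 of the antibody arm (adjusted p = 0.0573), nor without replicate 2 (adjusted p = 0.0652) or 4 (adjusted p = 0.0611) of the other. Nor was it called with the replicate block (adjusted p = 0.0525) or without replicates 1 and 4 of that arm (adjusted p = 0.0787). Of 75 nuclear oxidative phosphorylation genes Uqcrq (-0.37 ± 0.06 SE) and Ndufv3 (-0.26 ± 0.06 SE) fell and Sdha (0.18 ± 0.05 SE) rose, the same counts as when adjusted over the list alone. The list was called as lower (adjusted p = 0.0117, or adjusted p = 0.633 with an estimated correlation), but not without replicate 4 of the antibody arm (adjusted p = 0.0747) or replicate 1 of the other (adjusted p = 0.163). The call was also lost with fry (adjusted p = 0.213), without replicates 1 and 4 of the arm without antibody (adjusted p = 0.435), and after removal of length and GC trends, which took the median from -0.06 to -0.03 (adjusted p = 0.259). None of 13 mitochondrially encoded mRNAs was called, also when adjusted over the list alone. Their smallest p was that of mt-Nd2 (-0.22 ± 0.09 SE, adjusted p = 0.166). This gene was called without a filter (adjusted p = 0.0019), a fit that does not weigh its own spread, and with the stellate marker covariate (adjusted p = 0.0102). The list was not called (adjusted p = 0.0974). It was called as lower without replicate 4 of the antibody arm (adjusted p = 0.0412), or replicate 3 (adjusted p = 0.034) or 4 (adjusted p = 0.0224) of the other, and with the stellate marker level as a covariate (median -0.24 against -0.16, adjusted p = 0.00228).

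Of 18 tricarboxylic acid cycle genes and 14 heat shock genes none was called, also when adjusted over the list alone (list adjusted p = 0.997 and 0.992). The median and mean of each of these lists differed in sign within 0.02 of 0. Of 13 fatty acid synthesis genes Acsl3 rose (0.19 ± 0.05 SE) and of 23 lysosome genes the cathepsin gene Ctsl fell (-0.23 ± 0.06 SE). Each was the 1 called gene of its list, also when adjusted over the list alone, and the lists were not called (adjusted p = 0.317 and 0.149). The list of 24 cholesterol synthesis genes was not called either (adjusted p = 0.45). The lysosome list was called as lower without replicate 4 of the arm without antibody (adjusted p = 0.0224).

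Wnt and Notch genes included some that rose. Of 6 Wnt targets Lgr5, a stem cell receptor (0.72 ± 0.15 SE), and Rnf43, a ubiquitin ligase that damps Wnt receptors (0.23 ± 0.07 SE), rose, and 3 rose when adjusted over the list alone. The list was called as higher (adjusted p = 0.0432, or adjusted p = 0.407 with an estimated correlation), but not without replicate 1 of the antibody arm (adjusted p = 0.091), nor without replicate 1 (adjusted p = 0.143) or 4 (adjusted p = 0.0677) of the other. It was also lost without a filter (adjusted p = 0.0766), on log2(RPKM + 1) (adjusted p = 0.0589), after thinning to equal totals (adjusted p = 0.0687) and without replicates 1 and 4 of the arm without antibody (adjusted p = 0.312). Of 11 Notch pathway genes the ligand gene Jag1 (0.28 ± 0.05 SE) and the receptor gene Notch1 (0.29 ± 0.06 SE) rose, the same 2 when adjusted over the list alone. That list was not called (adjusted p = 0.149), except without replicate 2 of the antibody arm (adjusted p = 0.0377).

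Members of the remaining lists went both ways or seldom passed, and camera called none of these lists. Of 12 TGF-beta targets 2 fell, including the inhibitor gene Smad7 (-0.25 ± 0.07 SE), and the integrin gene Itgb6 (0.67 ± 0.12 SE) rose, and adjusted over the list alone 3 were lower and 2 higher (list adjusted p = 0.51). Of 17 FOXO targets 5 fell, including Cited2 (-0.56 ± 0.05 SE) and Klf6 (-0.32 ± 0.05 SE), and 2 rose, including the receptor gene Erbb3 (0.31 ± 0.06 SE). Adjusted over the list alone 6 were lower and 3 higher (list adjusted p = 0.188), while fry called this list as lower (adjusted p = 0.0245). Of 13 p53 targets the cell cycle inhibitor gene Cdkn1a (-0.38 ± 0.07 SE) and the kinase gene Plk2 (-0.29 ± 0.06 SE) fell, and adjusted over the list alone 5 were lower and 2 higher. The p53 list (adjusted p = 0.45) had a median of 0.00 above 0, while its mean (-0.05) and test pointed down. Of 20 BCL2 family and caspase genes Bmf (0.45 ± 0.12 SE) rose and Bcl2l11, which encodes BIM (-0.26 ± 0.07 SE), and the caspase inhibitor gene Cflar (-0.20 ± 0.05 SE) fell, the same counts as when adjusted over the list alone (list adjusted p = 0.848). Of 16 NRF2 targets 2 rose, including the glutathione transferase gene Gsta4 (0.50 ± 0.05 SE), and 3 fell, including the heme oxygenase gene Hmox1 (-0.37 ± 0.06 SE) and the transporter gene Abcc1 (-0.24 ± 0.05 SE), the same counts as when adjusted over the list alone (list adjusted p = 0.531).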

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

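In this part the thinning, the removal of trends, the fit without both control libraries that stand apart, the values of the G2/M list alone, the margin past 50%, the splits of single lists and the test of 1 control library for the ribosomal protein genes were chosen after seeing the data, the last 4 after results were seen. The real split gave 1144 genes and the highest of the other splits gave 1. Thus 1 of the 35 splits of the 8 libraries reached the real count. This argues against chance for the count of genes, but that share is the smallest that 35 splits can give. In the other splits the difference between the arms adds to the spread within a side and holds the calls down. Nor can the splits tell the antibody from any other difference in handling between the arms. For the lists, the real split gave 14 called lists and the highest of the other splits 12, and again 1 of the 35 splits reached the real count. Camera called lists in the other splits too, 1 to 8 in the 18 with 2 libraries of each arm on either side, where the arms are balanced, and 4 to 12 in the 16 with 3 and 1, although these gave 0 or 1 genes. A call of a single list is therefore weaker evidence than the count. The real split alone gave so small an adjusted p for the ATF4, ERK, inflammatory and mesenchymal lists, 1 of 35, while 2 of 35 did so for the interferon, hypoxia and YAP/TAZ lists, 3 for glycolysis, 4 for the epithelial, 5 for the Wnt and 11 for the oxidative phosphorylation list. The stellate marker level as a covariate left 1025 of the calls in place, which argues against stellate RNA left in the sort as their cause. Of the list calls it ended that of glycolysis and added those of the immediate early genes and the mitochondrially encoded mRNAs. The colour sort would remove stellate cells, and Acta2, the actin of activated stellate cells, chosen after its value was seen, had 6 counts over all 8 libraries.

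The fall of the ATF4 and amino acid response genes has 3 technical explanations that the tables argue against. With all libraries thinned to the smallest total, 23 members were still called lower, although every antibody library was deeper. Without any single control library at least 22 were called lower. After removal of trends with gene length and GC content the median log2 fold change was -0.36. For this list taken alone 1 of 35 splits gave so small an adjusted p, which argues against chance. That share is the smallest that 35 splits can give and is not adjusted for the 34 lists. In the real split camera gave adjusted p = 3.01e-22 (adjusted p = 0.185 with an estimated correlation), and the smallest of the other splits was 2.16e-14. The list was also called in 3 of the 18 balanced splits (smallest adjusted p = 0.000626). A response of the cells to the antibody treatment may therefore underlie it, as a hypothesis, but the labels name no control antibody, so that the neutralization of SHH and other effects of the added protein stay open.

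The fall of part of the ribosomal protein genes is less clear. Chance cannot be excluded for the list, since 5 of 35 splits gave so small an adjusted p, and it was called in 10 of the 18 balanced splits. Their 121 tested pseudogenes had a median log2 fold change of -0.13 ± 0.02 (bootstrap SE) with 14 lower and 0 higher. This argues against a shift of reads from the genes to their pseudogenes, which would have raised the pseudogenes. Reads shared in the same proportion in both arms would lower both, so this test cannot decide on shared reads. Removal of length and GC trends left a median of -0.0796 ± 0.014, or 69.8% of the value before. That is past 50% by 0.0226 ± 0.0087 (SE of a bootstrap over paired genes), which argues against such a trend as the whole cause in these libraries. The bootstrap SEs of this paragraph take the genes as independent and leave out the spread between libraries. Leaving out replicate 1 of the arm without antibody left -0.0602 ± 0.028, or 52.7%, past 50% by only 0.0031 ± 0.023, so the share of that library cannot be told apart from a response of the cells. Without both control libraries that stand apart the median was -0.03 and the list was no longer called (adjusted p = 0.133), and fry did not call it either (adjusted p = 0.089).

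The rise of part of the cell cycle genes was tested for depth and for 1 control library. After thinning 15 members of the G1/S and G2/M lists were called higher, of 20 before, which argues against depth. Without any single control library the largest adjusted p was 4.24e-06 for G1/S and 0.00417 for G2/M, which argues against 1 control library. Without both that stand apart the G2/M median fell from 0.11 to 0.04 and its call was lost (adjusted p = 0.312), while G1/S kept 0.09 of 0.17 (adjusted p = 0.000676). With fry G2/M was not called (adjusted p = 0.0829). Chance cannot be excluded for the list calls, since 5 of 35 splits gave so small a p for G1/S and 8 of 35 for G2/M, and each was called in 6 of the 18 balanced splits. This concerns the list calls and not the test of single genes. For that test the other splits gave at most 1 gene, a number that the difference between the arms holds down.

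A single library far from the other 3 of its arm was found in 24 of 298 sets of 4 values, where chance gives about 1 in 20, or 14.9. Replicate 1 without antibody and replicate 4 with antibody account for 8 each. Replicate 1 without antibody had 0.0246% of its counts in stellate markers, where its other 3 libraries had 0.0189 to 0.0194%. Its mean log2 CPM was 8.92 over the mitochondrially encoded mRNAs (the other 3 at most 8.35). It was also high for Col1a1 (15.43 CPM), Cyr61 (449.3 CPM), Ctsl (595.6 CPM), Tff2 (0.312 CPM) and Sytl2 (13.17 CPM), and low for Bcl2l11 (21.51 CPM, the others 23.24 to 23.51). Among the other libraries without antibody, Fut2 was low in replicate 3 (0.281 CPM), and Sptssb (1.92 CPM) and Cth (155.8 CPM) were high in replicate 4. In the antibody arm, replicate 4 was low for Fut2 (1.745 CPM), Aldoa (578 CPM) and the mean log2 CPM of the NRF2 targets (6.54), and high for Angptl6 (1.95 CPM), Gucy2g (1.01 CPM), Klf6 (268.6 CPM), Tnfaip3 (67.65 CPM) and Ctsl (449 CPM). Replicate 2 was high for Igf1r (39.63 CPM, the others 34.6 to 34.8) and low for Klf4 (74.05 CPM) and Mars (140.1 CPM), replicate 3 low for Esrp2 (62.06 CPM) and replicate 1 low for P4ha1 (57.57 CPM).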

How the results depend on the processing

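Voom with sample weights, thinning, trend removal and leaving out both libraries that stand apart were chosen after seeing the data. No called gene changed sign under any setting run, and the count of genes lay between 959 and 1663 except in the following. It was 115 with a minimum fold of 1.2 and 675 and 670 on log2(RPKM + 1) and log2(RPKM + 0.1). It was 2263 without both control libraries that stand apart, of which 944 were shared with the 1144, and without single libraries it ranged from 679 to 1485. The count of lists was 12 to 15, but 7 without both of those libraries and 0 with an estimated correlation; the cause was not tested. The depth limits low genes, Shh and Gli1 among them.

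The replicate numbers did not pair the libraries. Libraries of the same number correlated between -0.029 and 0.007 and others between -0.07 and 0.062, and 0 of 4 correlated best with their own number. With the replicate block 1005 genes and 12 lists were called, and the difference in total counts of 3238000 had p = 0.125, the smallest p that its exact sign-flip permutation can give. Without single libraries that difference ranged from 2550000 to 4081000, with an exact permutation p = 0.0571 where an antibody library was left out and p = 0.0286 where a control library was.

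The difference in the share of mitochondrially encoded mRNAs ranged from -0.663 to 0.039 percentage points without single libraries, the last without control replicate 1. That of the 10 most abundant genes ranged from -0.559 to 0.142, and was 0.0846 with the mitochondrial mRNAs left out (exact permutation p = 0.0571).

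Of the 103 called genes named here, 82 were called without any single library. The others, Tspan1, Gucy2g, Gas6, Dsp, Epcam, Fn1, Sdha, Aldoa, Acsl3, Top2a, H2-K1, Edem1, Bmf, Bcl2l11, Smad7, Ctgf, Rnf43, Ctsl, Tff3, Sytl2 and H2-D1, were lost without at least 1. A minimum fold of 1.2 ended 66 of the calls. On log2(RPKM + 1) and log2(RPKM + 0.1) 17 and 19 ended, all within that group but for Egr1, Cflar and Notch1. DESeq2 ended those of Gucy2g, Gas6, Egr1, Bcl2l11 and Rnf43, the covariate those of Gucy2g, Aldoa, Acsl3, Bcl2l11 and H2-D1, the block those of Gas6 and H2-D1, and thinning those of Epcam, Ndufv3, Bcl2l11, Rnf43, H2-D1 and Tff3. Without both libraries Tspan1 and Rnf43 were lost, and without a filter and after trend removal H2-D1.

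Results that changed direction were all uncalled. Ptch1 had -0.0039 with upper quartile scaling, -0.003 with the block, -0.0169 with voom weights, -0.0136 thinned, -0.0631 without both libraries, -0.0018 after trend removal and -0.0434 to 0.0329 without single libraries. The direction of a list is that of its test, and the values given are medians, which can keep their sign. The hedgehog list had -0.0197 without a filter, -0.0165 thinned, -0.034 with fry and -0.0705 to -0.0053 without single libraries. The tricarboxylic acid list had 0.0233 without a filter, 0.0189 with the stricter filter, 0.0198 with the block, 0.0324 with the covariate, 0.0278 on log2(RPKM + 1), 0.0183 with fry and -0.0127 to 0.0281 without single libraries. The heat shock list had 0.0079 with the covariate, 0.0108 on log2(RPKM + 1) and -0.0213 to 0.0173 without single libraries. Without single libraries BCL2 genes ranged from 0.0132 to 0.0523, with 0.0337 where control replicate 1 was left out, and NRF2 targets from 0.004 to 0.0797, the first without that library. Without both libraries NRF2 targets had -0.0089 and fatty acid genes -0.0307. Gcnt3 had 0.0014 with voom weights, 0.0133 without both libraries and -0.0433 to 0.0259 without single libraries. Krt20 had -0.0073, -0.0567 and -0.01 to 0.0475. The cause was not tested.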

Other observations

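The tests of this part were chosen after the genes concerned had been seen among those with small p. Several genes of mucous cells, some of them of the cells that line the stomach surface, rose with the antibody. These are singled out here after their values were seen. Besides Tff1, the mucin gene Muc5ac rose from 14.95 ± 2.25 to 25.18 ± 3.67 CPM (1.70-fold, adjusted p = 6.68e-05) and the mucin gene Muc5b rose 1.72-fold (adjusted p = 0.00042). The aspartic protease gene Ctse (1.30-fold), the junction gene Vsig1 (1.32-fold) and the annexin gene Anxa10 (1.48-fold) rose at levels of 91.17 to 141.9 CPM. Tff2 rose 4.35-fold from a low level, 0.226 ± 0.058 CPM (adjusted p = 0.00168).

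A candidate explanation is a shift of the cells toward a gastric pit mucous program. It was tested on 21 further genes listed for that program whose values had not been looked at when they were listed, of which 15 could be tested. Not all of them are particular to it. Their median log2 fold change was 0.0841, with 3 higher (Tff3, Sytl2 and Galnt7) and 0 lower (camera p = 0.00644, or p = 0.0365 with an estimated correlation). The test was first made on 26 genes, 19 of them tested, with a median of 0.1138 (camera p = 0.000468, or p = 0.0211 with an estimated correlation). After that result 5 of the 26 were left out, because their values may have been seen, so the test of the 15 was not a first look. The p values of this paragraph's list tests are unadjusted, and the splits were not run for these genes. The median was above 0 as the hypothesis needs, but the shift is small, and Cldn18 (0.04), Gcnt3 (-0.02) and Krt20 (0.02), which are also abundant in these cells, had adjusted p of 0.704, 0.874 and 0.906.

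Of 20 genes of the enzymes that charge tRNAs in the cytosol 9 fell and 0 rose, led by Cars (log2 fold change -0.36, adjusted p = 2.14e-05) and Mars (-0.32, adjusted p = 0.000139). Of 17 mitochondrial synthetase genes 0 fell and 1 rose (Lars2, 0.32). The 15 cytosolic genes outside the ATF4 list had a median of -0.15, which was -0.10 relative to the mitochondrial ones. The family was taken up because some of its members had been seen to fall, so these values do not show whether the ATF4 response reaches beyond the genes listed in advance.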
